A study of Rattus norvegicus with 12 samples.

How the data were processed

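Total RNA from cultures of rat cerebellar granule neurons was measured on 12 arrays, 3 in each of 4 groups, per the labels: low potassium at 3 h, GW5074 at 3 h, low potassium at 6 h and GW5074 at 6 h. Each group holds letters A, B and C. Per the labels, the title of GW_6h A ends in a suffix (e3_le1) unlike that of the other 11 titles (e1_le1), whose meaning is not given in the sources used here, and the array was kept in its group. The labels do not say whether the GW5074 cultures were also in low potassium, nor whether the letters stand for separate cultures, so the p-values below measure a spread between samples that may be technical. The number of arrays limits the precision.

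The deposited values are 1 intensity per probe set and array on a linear scale, from the values, for 31099 probe sets of an Affymetrix rat array, of which 57 are control probe sets. From the values, the authors scaled each array to the same mean of 150 after removal of the lowest and highest 2%. The scanner files, the summarisation method and the software are not given in the sources used here. Gene names come from the probe table's symbols and Entrez identifiers, matched to a rat gene table (assembly GRCr8) used only for names: 20826 probe sets carry 1 symbol, 436 several and 9780 none, and 20758 matched by Entrez identifier, for 14217 genes.

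The values were quantile-normalised between arrays over all non-control probe sets, 16 was added and log2 was taken. Log2 and fold changes are on this scale, while intensities with an SD are arithmetic means of the deposited values. Probe sets were kept when their mean over the 12 arrays was at or above the 40th percentile, which left 18625 probe sets for 10259 genes. The tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with 4 group means, no block and Benjamini-Hochberg adjustment at 0.05. The comparisons were GW5074 minus low potassium at 3 h, at 6 h and averaged over both times, the difference between the effects at the 2 times (interaction), and 6 h minus 3 h within each treatment. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

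A fit with a replicate block within time (the paired fit) was planned as an alternative. The pairing comes from the letters in the labels. It was checked on the values: after removal of the group means, the low-potassium and GW5074 arrays of a letter correlated across probe sets by 0.422, 0.21 and 0.542 at 3 h (A, B and C) and by 0.291, 0.651 and 0.573 at 6 h, and in each of the 6 pairs the array of the same letter was the best match. Across the times the same letter gave between -0.0668 and 0.182, so no pairing across times was used. The residual degrees of freedom are 8 without pairs and 4 with pairs. The paired fit is given beside the other wherever it changes a call. It was given that place in the text, and the naming rule was applied to it, only after the fit without pairs had been seen to call no probe set for GW5074.

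Gene lists were tested with camera in limma, with 1 probe set per gene, a preset correlation of 0.01 and adjustment over 28 lists within a comparison, and again with an estimated correlation. Members past the threshold were counted with adjustment over all probe sets and adjusted over the list alone. The 28 lists were: pro-apoptotic, anti-apoptotic, immediate early and AP-1; MAPK feedback, RAF-MEK-ERK, JNK and AKT pathway components, activity-dependent neuronal, granule neuron, AhR target, NRF2 target, ATF4 and amino acid response, ER chaperone, heat shock, cholesterol synthesis, glycolysis and hypoxia, FOXO target, p53 target, cell cycle, NF-kB and inflammatory, neurotrophin and growth factor, ion channel and calcium handling, histone deacetylase and chromatin, oxidative phosphorylation and ribosomal protein genes, and markers of astrocytes, oligodendrocyte lineage, microglia and macrophages, endothelial cells and fibroblasts, and Purkinje and GABAergic neurons.

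The genes named were, at 3 h and at 6 h, up to 10 largest rises and 10 largest falls past the threshold whose 3 GW5074 arrays all lay on one side of the 3 low-potassium arrays. For the other comparisons they were the 5 largest rises and 5 largest falls past the threshold. Where none passed, the 5 with the smallest p were taken. Up to 4 members with the smallest p of each list described, and preset genes (Jun, Fos, Atf3, Bcl2l11, Hrk, Egln3, Cdkn1a, Araf, Cyp1a1 and Bdnf), were added. A gene is represented by its probe set with the highest mean. Cyp1a1 was removed by the filter and is not tested. The groups, the tests without pairs, the lists, the naming rule and the first set of alternatives were fixed before the data were examined.

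RNA quality was read from the 3-prime minus 5-prime log2 difference of the actin and GAPDH control probe sets, with an exact two-sided sign-flip test over the 6 pairs. The log2 signal of the poly-A spike-in controls was tested in the same way. The position of each array between the 3 h and 6 h groups was computed on a scale on which 0 is 3 h and 1 is 6 h. The fits were tested on simulated data: of probe sets changed 2-fold at 6 h, 76.1% were recovered without pairs and 74.6% with pairs; of those changed 1.5-fold, 17.9% and 35.8%. In the same simulation 2 of 130 calls without pairs and 4 of 143 with pairs were false. The simulated noise and pair effects were drawn independently for each probe set. These numbers therefore give neither the share recovered nor the false calls in real arrays, where probe sets deviate together.

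The alternatives tried were the deposited values or median scaling in place of quantile normalisation, pseudocounts of 1 and 64, no filter or the 60th percentile, a block by letter over all arrays, a block within time, no mean-variance trend, a robust prior, array weights, only the groups compared, 1 probe set per gene and leaving out each array. Added after seeing the data were the poly-A spike-in batch as a block, only arrays with a low spike-in signal, leaving out both 6 h B arrays, the pair as a random block, and the paired fit under the other settings and without each pair.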

Results

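Gene expression was measured in rat cerebellar granule neuron cultures on 12 arrays, 3 per group: low potassium at 3 h and 6 h, and GW5074 at 3 h and 6 h. Granule neurons are commonly grown in raised potassium, and lowering it is a standard way to set off their death. No group is labelled as raised potassium or untreated, so the response to lowering potassium is not measured here. Changes from 3 h to 6 h cannot be told apart from time in culture. GW5074 is a small-molecule kinase inhibitor. The values are deposited intensities, and the number of arrays limits the precision. The 4 groups were compared over 18625 probe sets for 10259 genes. Each log2 change below is GW5074 minus low potassium, or 6 h minus 3 h. Log2 and fold changes are of the quantile-normalised values with 16 added. Intensities are arithmetic means of the deposited values, so their ratio differs from the fold.

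Time set the arrays apart more than treatment did. The first principal component held 54.8% of the variance, and the 3 h arrays lay between -0.0461 and 0.263 on a scale on which 0 is 3 h and 1 is 6 h. The 6 h arrays of letters A and C lay between 1.04 and 1.16, but those of letter B lay at 0.56 (low potassium) and 0.497 (GW5074). The actin 3-prime minus 5-prime difference, a sign of RNA quality, was higher with GW5074 in 6 of 6 pairs, by 0.112 ± 0.112 (SD, n = 6; exact two-sided sign-flip p = 0.03125). That of GAPDH was higher in 4 of 6 pairs (exact p = 0.21875). The actin p is the smallest that 6 pairs allow, and it was not adjusted for the other controls tested.

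**Figure D1:**
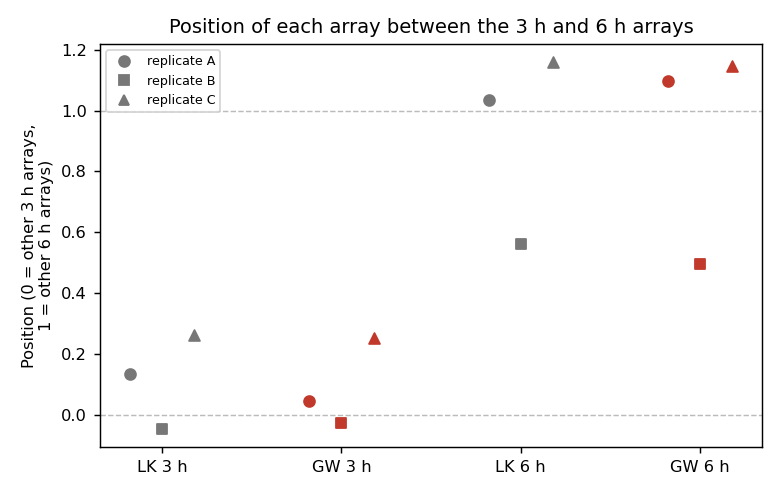
Position of each of the 12 arrays between the 3 h and 6 h groups (0 is 3 h, 1 is 6 h), by group and letter. The 6 h B arrays lie at 0.56 and 0.497, apart from the other 6 h arrays at 1.04 to 1.16.

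The comparison at 3 h asks which genes respond early to GW5074. Jun, an AP-1 transcription factor and a target of stress kinases, fell 2.11-fold (log2 -1.08, paired limma adjusted p = 0.0161). Its deposited intensity was 328.2 ± 35.5 in low potassium and 147.0 ± 18.5 with GW5074 (SD, n = 3 each). All 3 Jun probe sets had the same sign. No other named gene passed at 3 h. Anp32a, a phosphatase inhibitor and histone-binding protein, had 0.89, the urea-cycle enzyme Asl -0.72, the acyl-CoA dehydrogenase Acad11 -0.90 and Ranbp6 -0.61, none past the threshold. Of the preset genes, Fos had 0.10, Atf3 -0.28, the BH3-only genes Bcl2l11 and Hrk -0.09 and 0.31, Egln3 0.04, the cell cycle inhibitor Cdkn1a 0.09, the kinase Araf -0.03 and the neurotrophin Bdnf 0.13, none past the threshold with or without pairs. Single arrays moved these values: Atf3 lay between -0.613 (without LK_3h A) and -0.00193 (without LK_3h C), and Hrk between 0.17 (GW_3h C) and 0.557 (GW_3h A). Bcl2l11 lay between -0.143 (GW_3h C) and -0.0247 (LK_3h C) and Bdnf between 0.0477 (GW_3h C) and 0.196 (GW_3h A). The 3 AhR target genes tested, which respond to aryl hydrocarbon ligands, shifted up as a list (median 0.30, adjusted p = 0.0391, with pairs 0.0162), although 0 passed singly and 2 passed with pairs, adjusted over the list alone. Tiparp had 0.30, the cytochrome Cyp1b1 0.43 and the quinone reductase Nqo1 0.12. That list call was lost with an estimated correlation (adjusted p = 0.752 with an estimated correlation, with pairs 0.651), and in the fits without LK_3h B (adjusted p = 0.136), GW_3h A (0.166), GW_3h B (0.0803) or the filter on dim probe sets (0.0865). In the paired fit 4 more lists passed: oligodendrocyte lineage markers (median -0.16, adjusted p = 0.0216), FOXO target genes (-0.09, 0.0287) and cholesterol synthesis genes (-0.08, 0.0441) shifted down and ribosomal protein genes (0.02, 0.0287) up. Their adjusted p with an estimated correlation was 0.651, 0.48, 0.651 and 0.48 in that order, and 0 of their genes passed over all probe sets, 1 (Txnip) adjusted over the list alone. Among their members Sox10 had -0.61, Txnip -0.42, Foxo3 -0.26 and Fdps -0.21 (-0.102 without LK_3h C), not past the threshold. The actin difference was higher with GW5074 in 3 of 3 pairs at 3 h, most in pair C (0.298). In counts, limma without pairs called 0 probe sets, with 305 at an unadjusted p under 0.05 (931 expected by chance). Where arrays of a letter deviate together, a fit without pairs counts that deviation as error and can call too few. Its 0 calls are therefore no evidence of no effect, here or in the later GW5074 comparisons. The paired fit called 3, of which 1 rose and 2 fell, with 1218 at an unadjusted p under 0.05. The paired count was 0 without 3 h pair B, 0 without 3 h pair C, 6 without 6 h pair A and 0 without the mean-variance trend.

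**Figure D2:**
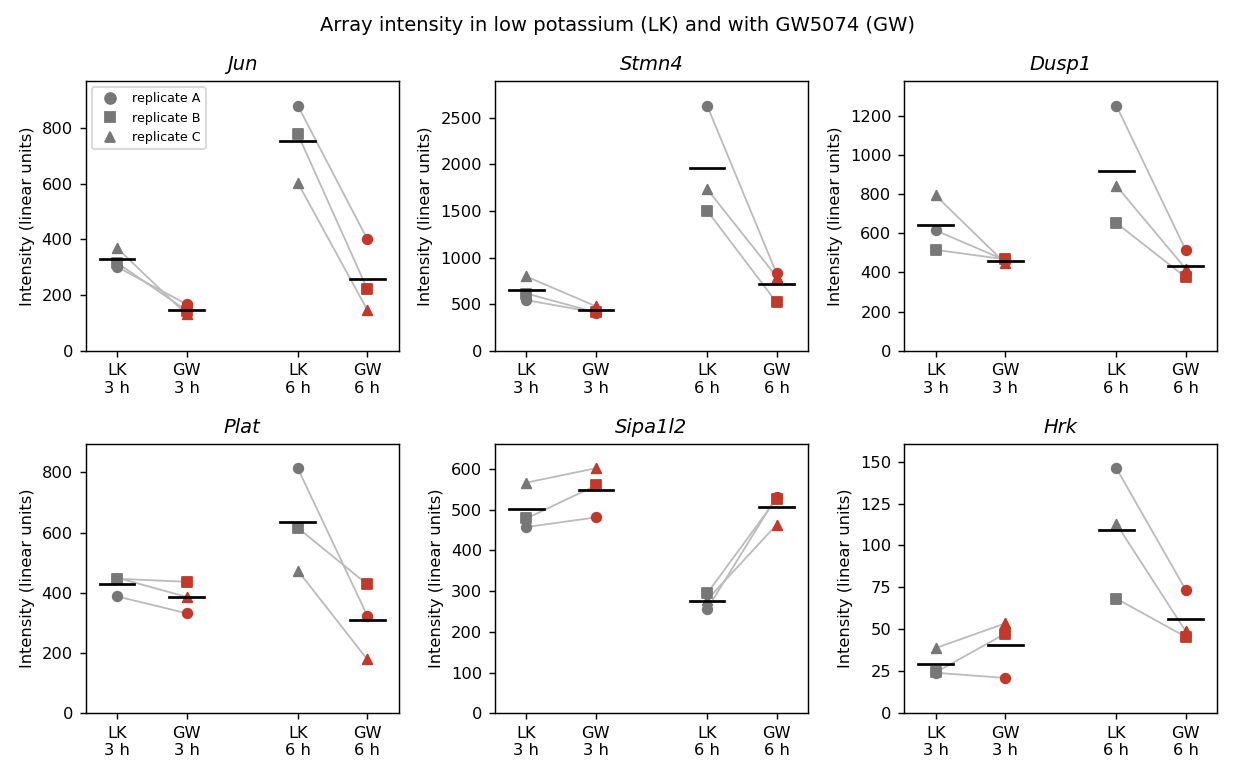
Deposited intensity of named genes in each array, by group, with group means. Jun fell with GW5074 at both times in the paired fit, from 328.2 to 147.0 at 3 h and from 753.5 to 256.1 at 6 h.

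The comparison at 6 h asks which genes differ with GW5074 at the later time. Of the genes whose 3 GW5074 arrays all lay on one side of the 3 low-potassium arrays, each by its brightest probe set, Jun and Stmn4, a stathmin-family regulator of microtubules, fell the most. Jun fell 3.11-fold (log2 -1.64, paired limma adjusted p = 2.69e-05, without pairs 0.0986) and Stmn4 2.78-fold (log2 -1.48, adjusted p = 6.78e-07 with pairs and 0.0970 without). Their deposited intensities were 753.5 ± 140 and 1957 ± 595 in low potassium, and 256.1 ± 130 and 714.8 ± 170 with GW5074 (SD, n = 3 each). Dusp1, a phosphatase of MAP kinases, fell by 1.05 (adjusted p = 2.7e-04, without pairs 0.351), and Plat, the tissue plasminogen activator, fell by 1.07 (5.08e-04, without pairs 0.551). Sipa1l2, which acts on the small GTPase Rap, rose the most of these genes, 1.80-fold (adjusted p = 2.12e-04 with pairs and 0.0986 without; deposited intensity 276.2 ± 19.4 against 507.3 ± 38.4). The other falls named by the rule were H4cl1 (-1.05), a histone H4 gene, Uggt1 (-0.92), a folding sensor of the endoplasmic reticulum, Eif2ak3 (-0.84), the stress kinase PERK, Id3 (-0.81), an inhibitor of helix-loop-helix factors, Rab30 (-0.71) and LOC100912031 (-0.71). The other rises were Rai1 (0.71), the RNA-binding Larp1 (0.70), the zinc transporter Tmem163 (0.69), Ttc22 (0.69), the metabotropic glutamate receptor Grm4 (0.65), the hedgehog co-receptor Boc (0.64), Zfp11 (0.61), the membrane protease Sppl2b (0.59) and the calmodulin-binding activator Camta2 (0.58). Their paired adjusted p lay between 0.00163 and 0.0429. With a pseudocount of 64 H4cl1 was -0.522 and Uggt1 -0.411. Without GW_6h C the value of H4cl1 was -0.581, and without LK_6h C that of Larp1 was 0.317. Without 6 h pair A the paired calls of H4cl1, Uggt1, Eif2ak3, Id3, Rab30, LOC100912031, Ttc22, Grm4, Boc, Zfp11 and Camta2 ended (adjusted p between 0.0699 and 0.385). Without 6 h pair B those of Uggt1, Rab30, LOC100912031, Zfp11 and Camta2 ended (0.0621 to 0.18). Without 6 h pair C the same happened to H4cl1, Uggt1, Id3, LOC100912031, Larp1, Ttc22, Zfp11, Sppl2b and Camta2 (0.0795 to 0.245). Leaving out 3 h pair B also ended the calls of H4cl1, Uggt1, Id3 and LOC100912031. That of Uggt1 ended without 3 h pair A too, and that of Id3 without 3 h pair C. Uggt1 and LOC100912031 (8 of 15 paired settings), Id3 (8 of 16) and H4cl1 (9 of 15) held least often. Jun, Stmn4, Dusp1, Plat, Sipa1l2, Rai1 and Tmem163 held without any single pair. Without pairs the smallest p belonged to Stmn4, Sipa1l2, Jun, Dusp1 and the calcium pump gene Atp2a2 (0.47, paired adjusted p = 0.00394, without pairs 0.351).

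Of the preset genes at 6 h, Atf3 fell by 0.98 in the paired fit (adjusted p = 0.0267), with overlapping groups and this call ended without 6 h pair A (-0.54, adjusted p = 0.276), 6 h pair B (0.0681) or 3 h pair B (0.0502). Without single arrays its value lay between -1.56 (LK_6h C) and -0.647 (LK_6h A). Hrk, which promotes cell death, had -0.72 (intensity 109.1 ± 39.0 against 55.95 ± 15.2, n = 3 each) and did not pass (paired limma adjusted p = 0.064). Fos (0.14), Bcl2l11 (0.06), Egln3 (-0.12), Cdkn1a (-0.03), Araf (-0.18) and Bdnf (0.03) did not pass either. The signs of Fos, Bcl2l11, Egln3, Cdkn1a and Bdnf turned when single arrays were left out, and Araf was -0.0978 without GW_6h A.

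In counts, limma without pairs called 0 probe sets at 6 h, with 895 at an unadjusted p under 0.05 (931 expected by chance) and a lowest adjusted p of 0.097. The paired fit called 349, of which 178 rose and 171 fell, for 200 genes (114 up and 86 down), with 3032 at an unadjusted p under 0.05. Of the 349, 348 had the same sign in all 3 pairs, the median size was 0.503, and 24 of the 25 that changed over 2-fold fell. The 349 were picked by a test on these same pairs, which favours a shared sign, so that agreement is no separate evidence. The pair as a random block gave 97 calls, a block by letter 7 and array weights 5. The paired count fell to 1 without the mean-variance trend (Stmn4), to 56 without 6 h pair A, whose GW5074 array has a title with a suffix unlike the other 11, and to 167 without 6 h pair C. Without 6 h pair A, 52 of the 56 were among the 349, and 15 of 33 genes named at 6 h still passed.

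**Figure D3:**
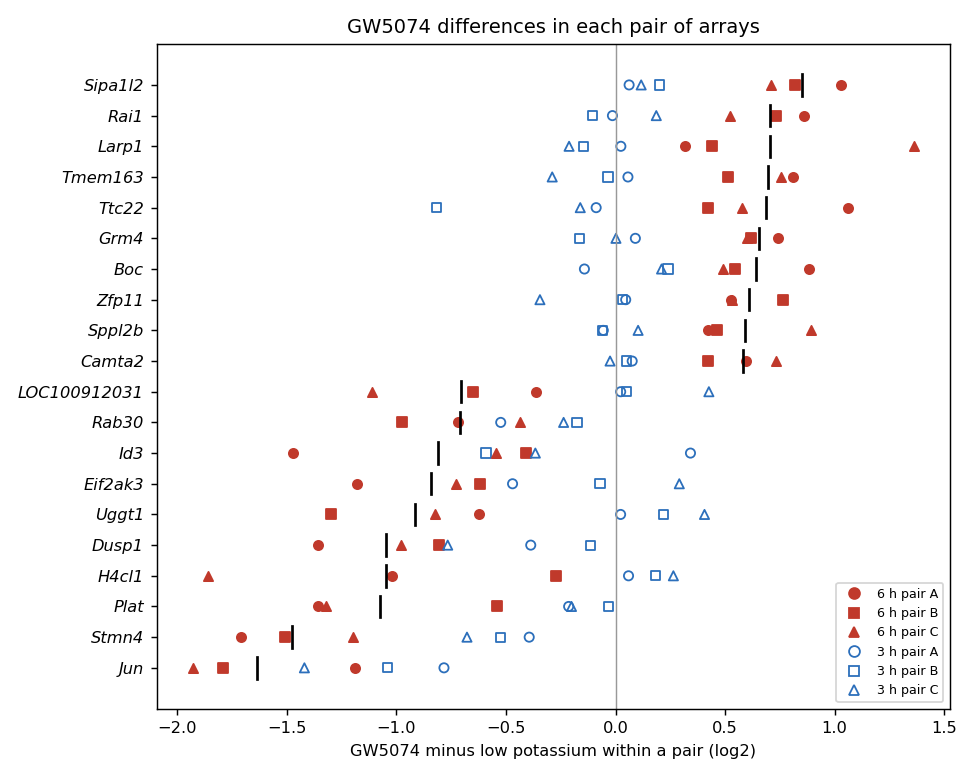
GW5074 minus low potassium (log2) in each pair of arrays, filled at 6 h and open at 3 h, for the genes named by the rule from the paired fit at 6 h. Bars are the 6 h means. Of the 349 probe sets called, 348 had the same sign in all 3 pairs, the pairs from which they were picked.

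Granule neuron genes shifted up with GW5074 at 6 h (32 genes, median 0.13, adjusted p = 0.04, but 0.785 with an estimated correlation; with pairs 0.0114, but 0.552). Slc17a7, the vesicular glutamate transporter, rose by 0.42 (paired limma adjusted p = 0.0042) and Kcnd2, a potassium channel, by 0.48 (0.0118), while 30 did not pass over all probe sets; 4 rose adjusted over the list alone. Without pairs the list's adjusted p was 0.317 without LK_6h A, 0.222 without LK_6h B, 0.0533 without GW_6h A, 0.364 without GW_6h C and 0.0527 with a 60th percentile filter. Its median was 0.226 without GW_6h B. Ion channel and calcium handling genes shifted up in the paired fit (26 genes, median 0.15, adjusted p = 0.0182, but 0.549 with an estimated correlation and 0.075 without pairs): 5 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone. Among these, Atp1b1, a subunit of the sodium pump, rose by 0.36, Kcnd3 by 0.50 and the kinase Camk2b by 0.31. Immediate early and AP-1 genes shifted down in the paired fit (25 genes, median -0.14, adjusted p = 0.0383, but 0.552 with an estimated correlation and 0.0618 without pairs): 4 fell, among them Jun, Jund (-0.60) and Atf3, and 2 rose, among them Ier5 (0.40); 5 fell and 2 rose adjusted over the list alone. FOXO target genes (22, median -0.15, paired adjusted p = 0.0182, but 0.504 with an estimated correlation) held Txnip, a thioredoxin-binding protein, which fell by 0.51; 0 others passed over all probe sets, and 4 fell and 1 rose adjusted over the list alone. ATF4 and amino acid response genes (36, median -0.08, 0.0383, but 0.664 with an estimated correlation; Atf3 alone passed, 2 adjusted over the list alone) and ribosomal protein genes (23, median -0.04, 0.0344, but 0.504 with an estimated correlation; 1 fell, 2 adjusted over the list alone) also shifted down in the paired fit. Without 6 h pair A the calls of Kcnd2 (0.132), Kcnd3 (0.261), Camk2b (0.0892) and Ier5 (0.148) ended. Without 6 h pair B that of Camk2b (0.0639) ended, and without 6 h pair C those of Camk2b (0.0685), Kcnd2 (0.0546) and Ier5 (0.115). Single arrays moved some members: Kcnd2 was 0.276 without LK_6h A and 0.77 without LK_6h B, Kcnd3 0.29 without LK_6h A, and Ier5 0.143 without GW_6h B and 0.754 without LK_6h B. Txnip was -0.206 without GW_6h A and -0.87 without GW_6h B. Without pairs the FOXO, ATF4 and ribosomal lists had adjusted p of 0.12, 0.122 and 0.075.

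MAPK feedback genes, which damp kinase signalling, did not shift as a list at 6 h (17 genes, median 0.05, mean -0.04, adjusted p = 0.652, with pairs 0.605). Dusp5 rose by 0.44 (paired limma adjusted p = 0.0106), and Dusp1 and Gadd45g (-0.58, 0.00582) fell; adjusted over the list alone, 1 rose and 2 fell. The call of Dusp5 ended without 6 h pair B (0.0749) and that of Gadd45g without 6 h pair A (0.0691). Dusp5 was 0.198 without GW_6h B, and Gadd45g was -0.236 without GW_6h C and -0.923 without LK_6h C. Pro-apoptotic genes did not shift either (20 genes, median -0.03, adjusted p = 0.641, with pairs 0.517). Bid, which links death receptors to mitochondria, rose by 0.42 (0.046), a call that held in 6 of 16 paired settings and ended without any of the 6 pairs (adjusted p between 0.0623 and 0.279) and without the trend, and adjusted over the list alone 1 rose and 2 fell. Bbc3 had -0.44 (-0.181 without LK_6h A) and Trib3 -0.48 (0.00963 without LK_6h A), not past the threshold. Microglia and macrophage markers shifted down in the paired fit beside these lists (14 genes, median -0.13, adjusted p = 0.0471, with 0 genes past the threshold; adjusted p = 0.664 with an estimated correlation). Astrocyte markers did not pass as a list (15 genes, median -0.11, paired adjusted p = 0.0668), although Id3 fell, and 3 fell adjusted over the list alone; Gja1 had -0.42 (-0.0687 without GW_6h C, -0.87 without GW_6h B), Fabp7 -0.41 (-0.252 without GW_6h A, -0.68 without GW_6h B) and Aqp4 -0.19 (0.0592 without GW_6h C), not past the threshold. The actin difference was higher with GW5074 in 3 of 3 pairs at 6 h, by 0.111 on average. The log2 signal of the poly-A spike-in controls was lower with GW5074 in 3 of 3 pairs at 6 h (-0.568 in A, -0.156 in B and -0.645 in C). Its mean difference was -0.456 at 6 h and 0.0127 at 3 h. Over the 6 pairs of both times the spike-in signal was lower in 4 and higher in 2 (exact two-sided sign-flip p = 0.21875).

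**Figure D4:**
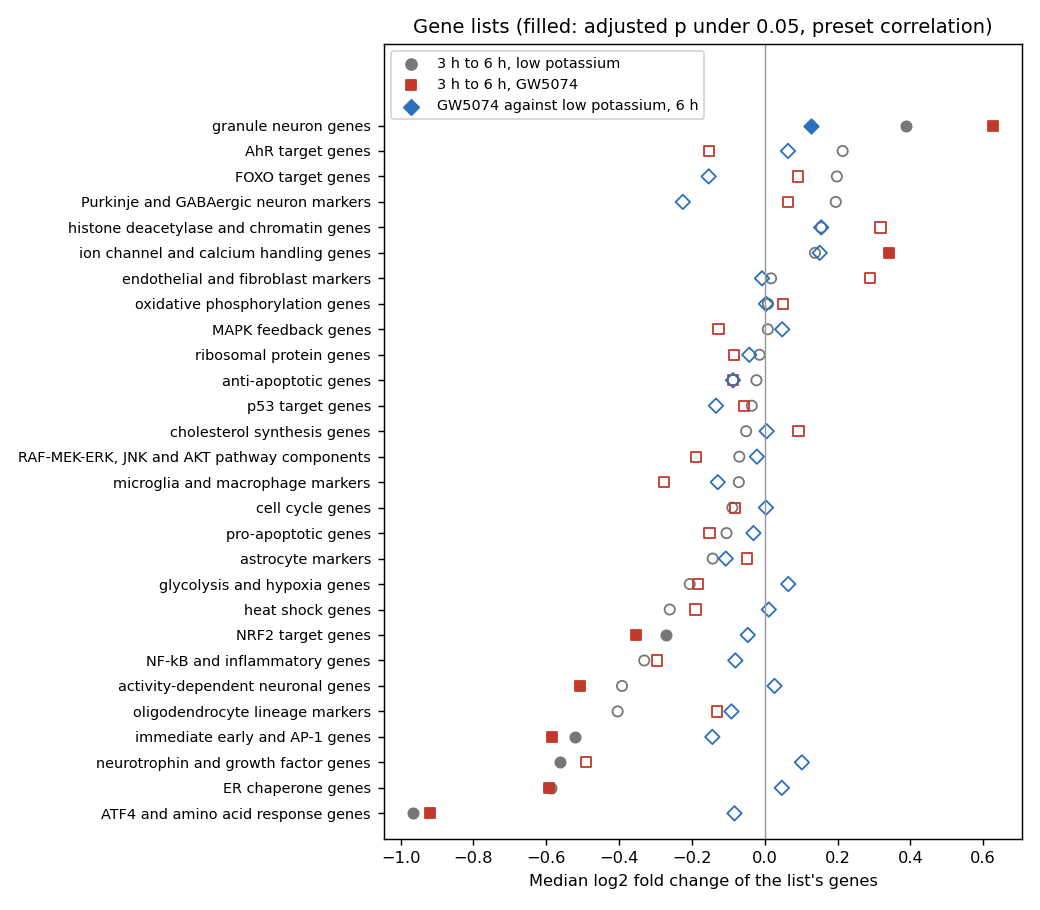
Median log2 change of the genes of each of the 28 lists in 3 comparisons, in the fit without pairs. Filled points passed an adjusted p of 0.05 with the preset correlation, as granule neuron genes did in all 3, and none passed with an estimated correlation.

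Averaged over both times, and by the brightest probe set of each gene, Jun and Stmn4 fell most, by 1.36 (paired limma adjusted p = 2.52e-06, without pairs 0.0676) and 1.00 (1.21e-06, without pairs 0.0873). Dusp1 (-0.73), Sh2d3c (-0.72) and Plat (-0.61) also fell in the paired fit. Sipa1l2 (0.49), Pitpnm2 (0.37), Rai1 (0.36), Dusp5 (0.32), a phosphatase of ERK kinases, and Rasd2 (0.27), a small GTPase, rose. Without GW_6h B, Pitpnm2 was 0.216 and Dusp5 0.198. Without 3 h pair A the calls of Rai1 (0.139), Rasd2 (0.173), Dusp5 (0.12), Pitpnm2 (0.095), Sh2d3c (0.0662) and Plat (0.0598) ended. Rai1 (7 of 16 paired settings), Rasd2 (8 of 16), Dusp5 (9 of 16), Sh2d3c (10 of 15) and Pitpnm2 (11 of 16) also lost their calls without other pairs. The calcium channel subunit Cacnb1 had 0.51 and did not pass (paired adjusted p = 0.0886). Fos had 0.12, Atf3 -0.63, Bcl2l11 -0.02, Hrk -0.21, Egln3 -0.04, Cdkn1a 0.03, Araf -0.11 and Bdnf 0.08, none past the threshold. Without single arrays Hrk lay between -0.337 (without LK_6h B) and -0.0831 (without GW_3h A), and Araf between -0.145 (without GW_3h A) and -0.0659 (without GW_3h C). FOXO target genes shifted down in the paired fit (median -0.07, adjusted p = 0.00129, but 0.307 with an estimated correlation and 0.0618 without pairs); Txnip fell by 0.47 and 5 fell adjusted over the list alone. ATF4 and amino acid response genes shifted down as well (median -0.03, paired adjusted p = 0.0218, but 0.69 with an estimated correlation and 0.121 without pairs), with 0 genes past the threshold over all probe sets and 1 adjusted over the list alone. The actin difference was higher with GW5074 in all 6 pairs. Limma called 0 probe sets without pairs, with 473 at an unadjusted p under 0.05 (931 expected by chance), and 44 with pairs (11 rose, 33 fell), with 1880 at an unadjusted p under 0.05. Other fits gave 18 with the pair as a random block, 6 with array weights, 4 with a block by letter and 1 with 1 probe set per gene. The paired count was 4 without the mean-variance trend, 15 without 3 h pair A, 23 without 3 h pair B and 24 without 3 h pair C.

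Whether the effect of GW5074 differed between 3 h and 6 h was tested as an interaction. It was more positive at 6 h for Cpne5 (0.83), a calcium-binding copine, Tmem163 (0.78), Ncs1 (0.78), a neuronal calcium sensor, L1cam (0.77), an axonal adhesion molecule, and Atp1b2 (0.77), a subunit of the sodium pump. It was more negative for Cdr2 (-1.72), Anp32a (-1.25), Pik3r1 (-1.07), a regulatory subunit of PI3-kinase, Pxdc1 (-1.04) and Dtna (-0.98), a dystrobrevin, which ranged from -1.58 without LK_6h B to -0.411 without GW_6h B. Cdr2 was -1.14 without GW_6h C. These passed in the paired fit (adjusted p between 0.0313 and 0.0492), but each in only 6 to 9 of 16 paired settings, and none without 6 h pair A. The smallest p without pairs belonged to Rassf8 (0.74), Anp32a, Ptprf (0.73), Dglucy (1.08) and Sdcbp (-0.64), none of which passed in that fit. Granule neuron genes (median 0.21, adjusted p = 0.00839, with pairs 0.0013) and ion channel genes (0.21, 0.0483, with pairs 0.0123) shifted up and ribosomal protein genes shifted down (-0.08, 0.00839, with pairs 0.00209). With an estimated correlation the adjusted p was 0.808 for each, and with pairs 0.636, 0.636 and 0.387. Of the ion channel list Atp1b1 passed with pairs (0.39, in 6 of 16 settings), and 7 were higher adjusted over the list alone, against 4 granule neuron genes higher and 1 ribosomal protein gene lower. Leaving out 1 array ended all 3 list calls for LK_3h C, GW_3h A, LK_6h A, LK_6h B and GW_6h C (granule neuron adjusted p = 0.217, 0.216, 0.305, 0.0939 and 0.309 in that order), and GW_3h B ended that of ion channels (0.292). The ion channel median was 0.0731 without LK_6h A, 0.113 without GW_3h A and 0.324 without GW_3h C. That of ribosomal proteins was -0.0389 without LK_3h C, -0.0385 without GW_6h C and -0.117 without LK_6h C, and that of granule neuron genes 0.131 without LK_3h C. The ion channel call also ended with values as deposited (0.0532), median scaling (0.0668), a pseudocount of 64 (0.0539) and no filter (0.169), and the ribosomal call with array weights (0.196, median -0.0399). The ribosomal median was -0.22 with values as deposited and -0.158 with median scaling. Limma called 0 probe sets without pairs, with 645 at an unadjusted p under 0.05 (931 expected by chance), and 37 with pairs (18 up, 19 down), with 2499 at an unadjusted p under 0.05. The paired count was 0 without the filter on dim probe sets, 0 without the trend, 4 with a pseudocount of 1, 63 with median scaling, 0 without 6 h pair A, 154 without 6 h pair B, 2 without 3 h pair A and 1 without 3 h pair B, 3 h pair C or 6 h pair C. Across probe sets the effects at 3 h and 6 h had a Pearson r of -0.0707 (genes are not independent replicates), which was 0.000819 without LK_3h C, and 161 of the 349 probe sets called at 6 h (46.1%) had the same sign at 3 h.

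From 3 h to 6 h in low potassium, genes of the ATF4 and amino acid response fell together, and genes of granule neurons rose. Of 36 ATF4 list genes 28 fell and 0 rose (29 fell adjusted over the list alone; median -0.97, adjusted p = 5.47e-11, but 0.256 with an estimated correlation). Among them were the cystine transporter gene Slc7a11 (-1.80), the translation repressor Eif4ebp1 (-2.30), the serine synthesis enzyme Psph (-1.36) and the seryl-tRNA synthetase Sars1 (-0.88). Of 32 granule neuron genes 12 rose and 3 fell (17 and 3 adjusted over the list alone; median 0.39, adjusted p = 3.18e-04, but 0.669 with an estimated correlation), with rises of Fat2 (1.90), a cadherin, Rbfox3 (1.44), the NeuN antigen, Cbln1 (1.42), a synapse organiser, and Neurod1 (1.21). By the brightest probe set of each gene, the largest fall was that of Reg3b, a secreted lectin, 30.3-fold on the normalised scale (log2 -4.92, limma adjusted p = 6.37e-04; -4.26 without LK_6h A and -5.72 without LK_6h B). Its deposited intensity was 8106 ± 1740 at 3 h and 341.9 ± 345 at 6 h (SD, n = 3 each). Its relatives Reg3a (-3.43) and Reg1a (-2.93) fell too, as did Perm1 (-3.19) and Mlf1 (-2.94). Angptl4, an inhibitor of lipoprotein lipase, rose 5.08-fold on the normalised scale (deposited intensity 49.7 ± 20.8 at 3 h and 315.4 ± 70.5 at 6 h), followed by the MAP kinase kinase Map2k6 (2.30), Tspan1 (2.24), the lipid-droplet protein Cidec (2.03) and Tmem178a (2.01).

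Further lists, 4 in all, shifted down in low potassium. ER chaperone genes (22, median -0.59, adjusted p = 0.014, but 0.881 with an estimated correlation; 6 fell, 11 adjusted over the list alone) held Edem1 (-1.14) and Sdf2l1 (-1.82). Immediate early and AP-1 genes (25, median -0.52, adjusted p = 0.0216, but 0.881 with an estimated correlation) had 10 that fell, among them Nr4a1 (-1.40) and Nr4a3 (-1.60), and 2 that rose, Jun (1.13, limma adjusted p = 0.0083) and Egr1 (0.95); 12 fell and 2 rose adjusted over the list alone. Neurotrophin and growth factor genes (18, median -0.56, adjusted p = 0.0285, but 0.755 with an estimated correlation) had 9 that fell, such as Tgfb2 (-1.41), Igfbp3 (-1.55) and Bdnf (-0.96), and 1 that rose, the receptor gene Igf1r (1.61), with the same numbers adjusted over the list alone. NRF2 target genes (22, median -0.27, adjusted p = 0.0356, but 0.755 with an estimated correlation) had 6 that fell, such as the haem-degrading enzyme Hmox1 (-1.61), and 1 that rose (7 and 1 adjusted over the list alone). Without LK_6h C the adjusted p of these 4 lists was 0.085, 0.0931, 0.0844 and 0.0844, and the ER chaperone median was -0.356. The ER chaperone and NRF2 calls were also lost without LK_3h A (0.0551 each), that of NRF2 without LK_6h B (0.0529) and that of neurotrophins without GW_3h B (0.101) or the filter (0.0919, where its median was only -0.201). With a 60th percentile filter the immediate early (0.324, median only -0.296), neurotrophin (0.175, median -0.377) and NRF2 (0.0945, median -0.368) calls ended. The immediate early median was -0.284 with a pseudocount of 64, and that of NRF2 target genes -0.174 without the filter, both calls holding. Pro-apoptotic genes did not shift as a list (20, median -0.10, adjusted p = 0.833): Hrk rose by 1.43 (0.00316) and Casp2 by 0.83 (0.017), while Bid fell by 0.43, Diablo by 0.39 and 1 more; 3 rose and 5 fell adjusted over the list alone. The calls of Casp2 ended without LK_3h B (0.083), LK_6h A (0.0753) or LK_6h C (0.0682), and those of Bid and Diablo without LK_3h A (0.115 and 0.134), LK_3h B (0.07 and 0.137), LK_6h A (0.0912 and 0.132) or LK_6h C (0.0668 and 0.0748) and under median scaling (0.117 and 0.0993). FOXO target genes did not pass as a list (22, median 0.20, adjusted p = 0.0991), although 8 rose, among them Cited2 (1.51), Pik3ip1 (1.46), Sesn1 (1.35) and Foxo3 (0.89), and 4 fell (9 and 4 adjusted over the list alone). Astrocyte markers moved apart: the structural protein Gfap rose by 1.87, while Ntsr2 fell by 1.85 and Agt by 1.49 (15 genes, 1 up and 3 down, also adjusted over the list alone; list adjusted p = 0.789). In counts, limma called 4205 probe sets (2160 rose, 2045 fell) for 2608 genes, 1006 of them over 2-fold. The count was 2180 without LK_3h B, 2316 without LK_6h C, 2584 without LK_6h A, and 57 on the arrays with a low poly-A spike-in signal, which leave 1 array at 3 h per treatment, assumed to vary like the other groups.

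From 3 h to 6 h with GW5074 the changes were alike in direction: 2910 probe sets were called in both treatments, all of them in the same direction, 1482 up and 1428 down, and the changes had a Pearson r of 0.84 across probe sets. The arrays of a letter deviate together within a time (r between 0.21 and 0.651), which makes the time changes of the treatments alike even where nothing changes, so neither number is compared with chance here. By the brightest probe set of each gene, the largest rises were Map2k6 (2.70), Sema3g (2.46), a secreted semaphorin, Tcerg1l (2.32), Ppp1r1b (2.26), the phosphatase inhibitor DARPP-32, and Vsnl1 (2.24), a neuronal calcium sensor. The largest falls, ranked in the same way, were Reg3b, 31.2-fold on the normalised scale (log2 -4.96, limma adjusted p = 4.02e-04; -4.38 without GW_6h A and -5.91 without GW_6h B), Reg3a (-3.68), Xirp1 (-3.10), Reg1a (-3.06) and Perm1 (-3.00). The deposited intensity of Reg3b was 8616 ± 1340 at 3 h and 382.6 ± 451 at 6 h (SD, n = 3 each). Of the ATF4 list 27 of 36 genes fell (median -0.92, adjusted p = 4.31e-12, but 0.2 with an estimated correlation; 29 adjusted over the list alone), with Eif4ebp1 (-2.45) and Psph (-1.62), and of the granule neuron list 19 of 32 rose and 1 fell (median 0.63, adjusted p = 3.76e-07, but 0.365 with an estimated correlation; 20 and 1 adjusted over the list alone), with Rbfox3 (1.67) and Syn2 (1.28), a synaptic vesicle protein. Ion channel genes shifted up (26, median 0.34, adjusted p = 0.00791, but 0.594 with an estimated correlation; 9 rose and 0 fell, 11 adjusted over the list alone), such as the calcium pump Atp2b2 (1.02) and the sodium channel Scn3a (1.23). Immediate early and AP-1 genes (25, median -0.58, or -0.352 with a pseudocount of 64, adjusted p = 7.17e-04, but 0.594 with an estimated correlation; 8 fell, 11 adjusted over the list alone) held Atf3 (-2.37), Nr4a1 (-1.55) and Klf6 (-1.21). ER chaperone genes (22, median -0.59, adjusted p = 0.00421, but 0.594 with an estimated correlation; 6 fell, 9 adjusted over the list alone), NRF2 target genes (22, median -0.35, adjusted p = 0.00659, but 0.594 with an estimated correlation; 6 fell, 6 adjusted over the list alone) and activity-dependent neuronal genes (19, median -0.51, adjusted p = 0.0389, but 0.594 with an estimated correlation; 6 fell and 2 rose, 8 and 3 adjusted over the list alone) shifted down, with Sel1l (-1.02), Hmox1 (-1.88) and Bdnf (-1.07). The call of activity-dependent genes ended without GW_3h C (0.0804) or GW_6h C (0.191), and that of ER chaperones without GW_6h C (0.056), where their median was -0.369 and that of NRF2 targets -0.229. Array weights ended both (0.0664 each), and a 60th percentile filter ended those of activity-dependent (0.248) and immediate early genes (0.0644). In counts, limma called 4657 probe sets (2443 rose, 2214 fell) for 2815 genes, 1130 of them over 2-fold. The count was 2452 without GW_6h A, 2668 without GW_3h B, 2930 without GW_6h C, 3047 without GW_3h A, 581 on the arrays with a low poly-A spike-in signal, 8943 with array weights and 3010 with 1 probe set per gene.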

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

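In this part the tests of the splits without pairs for GW5074, of non-neuronal cells, of the poly-A spike-in batch, of separate preparations and of letter B were chosen after the results they bear on were seen. The paired fit called 37 probe sets whose GW5074 effect differed between 3 h and 6 h, a difference between the times by its own test. Of 32 ways to swap treatments within pairs, 2 gave as many (real 37, highest other 44), so chance is not excluded; the other is the swap of every 6 h pair, which turns the difference into the average, and without it the highest was 24. For the average effect 1 of 32 did (44, highest other 37), the real one. That share is under 0.05 but is the smallest these swaps allow, and it was not adjusted for the other swap tests. The paired fit was also given its place after the other fit had called 0, and its count was 4 without the trend. Chance is therefore not excluded for the average either. At 3 h and 6 h the pairs allow 4 swaps, too few for a share under 0.05: 1 of 4 gave as many calls in each (3 and 349, highest other 0 in both).

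Without pairs, the 3 h and 6 h arrays of a treatment split in 10 ways, too few for a share under 0.05: the real split gave 4205 calls in low potassium and 4657 with GW5074, the 1 split of 10 with as many, and the highest other gave 0 in both. The GW5074 comparisons called 0 without pairs, so every split gives as many (10 of 10 at 3 h, highest other 0, and 10 of 10 at 6 h), whatever the cause, and these splits say nothing about chance. At 6 h the highest other was 531, for LK_6h A, LK_6h C and GW_6h C against LK_6h B, GW_6h A and GW_6h B, and 3 of the other splits made calls, which points to a structure of the samples. The same holds for the average and the interaction (100 of 100 splits drawn, real 0, highest other 92 and 238), whose splits also ignore the pairs.

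The first pattern weighed is the set of 349 paired calls at 6 h. If RNA degradation were the cause, the 3 h pair with the largest actin gap should shift the same probe sets. That is pair C (0.298, against 0.113, 0.185 and 0.035 in the 6 h pairs), and the ratio of its median shift to that at 6 h was -0.0591. In that pair the actin gap went without the shift. It is 1 pair at another time, with a GAPDH gap of 0.044 against 0.0492, 0.0609 and -0.0434 at 6 h, so it cannot decide. The poly-A spike-in signal was lower with GW5074 at 6 h (mean log2 difference -0.456, against 0.0127 at 3 h). A labelling difference between the treatments at 6 h was not tested and stays open. For fewer non-neuronal cells, their 38 pooled markers had a median of -0.103 (95% interval across genes -0.145 to -0.0394) against -0.571 for the probe sets that fell. Those probe sets were picked because they fell, and genes are not independent replicates, so the comparison cannot decide. The markers fell by a small amount, and a small loss of these cells stays open. Probe sets called from the other pairs (59 without A, 296 without B and 163 without C) were followed in the pair left out. They shifted there by 0.987 (A), 0.391 (B) and 0.51 (C) times as much, with 96.6%, 84.5% and 87.1% of one sign. For these probe sets a single pair as the source is argued against. Only 52 of the 349 were called without 6 h pair A, so for the calls lost without it that pair as the source stays open. An effect of GW5074 remains a hypothesis, found and tested on the same arrays, and its count rests on the mean-variance trend (1 call without it).

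The second pattern is the difference between the 3 h and 6 h arrays. A labelling batch marked by the poly-A spike-in signal, high in 4 of the 3 h arrays, should leave letter A with little change, yet letter A shifted 1.04 times as much as letters B and C over 4560 probe sets (0.713 against 0.688). Separate culture preparations at the 2 times stay open: of 12 comparisons of the same letter across times, 2 had a correlation over 0.1, as separate preparations would give. They cannot be told apart from time in culture, which the design names and which was not tested separately.

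The third pattern is the place of the 6 h B arrays, at 0.56 and 0.497 between the times. A swap of letter B between the times is argued against by the 3 h B arrays, at -0.0461 and -0.0262, within the range of the other 3 h arrays widened by its width. For arrays of 3 h labelled as 6 h, probe sets called from 6 h pairs A and C shifted in pair B by 0.391 of their size. That is short of the bound of 0.5 set for excluding it and above the 0.25 set for supporting it (the bound was changed once after this value was seen, then put back). The 3 h pairs gave between -0.0805 and -0.0205. Of these 296 probe sets 84.5% kept their sign in pair B, against 39.9% to 46.3% in the 3 h pairs. The highest position of a 3 h array was 0.263. These values argue against pair B being arrays of 3 h, although the bound for excluding it was not reached. A slower response in that pair may be another reason, and no test of it was run. Leaving out both 6 h B arrays gave 5519 calls from 3 h to 6 h in low potassium and 5824 with GW5074.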

How the results depend on the processing

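Chosen after seeing the data were the spike-in batch block, low-spike arrays, leaving out both 6 h B arrays, the pair as a random block, and the paired fit under other settings and without each pair. Counts at 3 h, 6 h, on average and for the interaction, 0 each, became 3, 349, 44 and 37 with a block within time. Of the lists it called 5 at 3 h, 7 at 6 h and 2 on average, and the same 3 for the interaction; it changed no other call that it can test, and it cannot test the change from 3 h to 6 h. They became 7 (6 h) and 4 (average) with a block by letter, 5 and 6 with array weights, 97 and 18 with the pair as a random block, and 1 (average) with 1 probe set per gene. Leaving out 1 array gave 0 to 3 at 6 h, 0 to 3 on average, and 0 to 0 at 3 h and for the interaction. The time counts (4205 and 4657) ranged from 2180 to 4941 and from 2452 to 5327, fell to 57 and 581 on low-spike arrays (fewer samples), and the second to 3010 with 1 probe set per gene (fewer tested) and rose to 8943 with array weights; a spike-in block gave 2833 and 3236. The correlation of -0.0707 ranged from -0.109 to 0.000819. Paired counts at 3 h (3) became 5 with median scaling, 0 with no filter, 1 with 1 probe set per gene, 0 with no trend, 5 with the groups compared only, and 0 to 6 without a pair. At 6 h (349) they became 148 with no filter (more tested), 220 with 1 probe set per gene, 1 with no trend, 232 with the groups compared only, and 56 to 294 without a pair. On average (44) they became 19 with no filter, 24 with 1 probe set per gene, 4 with no trend, and 15 to 48 without a pair. For the interaction (37) they became 63 with median scaling, 4 with pseudocount 1, 0 with no filter, 57 with the 60th percentile, 0 with no trend, and 0 to 154 without a pair. Without the trend the prior degrees of freedom were 3.88 in place of 12.1. List calls at 3 h (1) became 3 as deposited, 3 with median scaling, 0 with no filter, 3 with a block by letter, and 0 to 7 without an array. At 6 h (1) they became 3, 3, 2 with pseudocount 1, 0 with the 60th percentile, 4 by letter, 3 with weights, and 0 to 12. On average (0) they became 1, 4, 1 with no filter, 1 with the 60th percentile, 1 by letter, 3 with weights, and 0 to 6. In low potassium (6) they became 3 with the 60th percentile, and 2 to 6; with GW5074 (7) 11 as deposited, 13 with median scaling, and 5 to 11; for the interaction (3) 0 to 8. The ion channel call of the interaction ended as deposited (0.0532), with median scaling (0.0668), pseudocount 64 (0.0539) and no filter (0.169), and the ribosomal one with weights (0.196). Signs turned for uncalled genes only: with median scaling Cdkn1a at 6 h (0.0415) and Bcl2l11 on average (0.00956), with weights Bdnf (-0.029) and Fos (-0.18) at 6 h and Cdkn1a (-0.0117) and Egln3 (0.0305) on average, and without both 6 h B arrays Fos at 6 h (-0.282) and Bcl2l11 (0.0041), Cdkn1a (-0.111), Egln3 (0.00599) and Fos (-0.0918) on average. Without 1 array, 3 h values ranged from -0.11 to 0.0504 (Araf), -0.062 to 0.232 (Cdkn1a), -0.47 to 0.105 (Cdkn1b), -0.0381 to 0.109 (Egln3), -0.0112 to 0.168 (Fos) and -0.0899 to 0.268 (Nqo1); 6 h values from -0.418 to 0.0592 (Aqp4), -0.156 to 0.317 (Bcl2l11), -0.186 to 0.163 (Bdnf), -0.569 to 0.386 (Cdkn1a), -0.815 to 0.032 (Ddit3), -0.54 to 0.233 (Egln3), -0.553 to 0.527 (Fos) and -0.796 to 0.00963 (Trib3); average values from -0.125 to 0.112 (Bcl2l11), -0.0281 to 0.146 (Bdnf), -0.237 to 0.24 (Cdkn1a), -0.252 to 0.135 (Egln3) and -0.228 to 0.312 (Fos). Median scaling moved the share of rises among time calls with GW5074 to 62.2% from 52.5% and among paired 6 h calls to 60.9% from 51.0%. Under any scaling the median change of all probe sets was at most 0.0501. Apart from fewer samples or probe sets tested, the cause was not tested. Signs were checked for the named genes only. No alternative reversed a named gene called from 3 h to 6 h, although some of those calls ended, such as those of Casp2, Bid and Diablo. Many more ended on the low-spike arrays, which leave 1 array at 3 h per treatment, among them genes with the largest changes. There, in low potassium, Reg3b was -5.08, Eif4ebp1 -2.42, Slc7a11 -2.06, Hrk 1.61 and Jun 1.22. With GW5074, Reg3b was -5.07, Perm1 -2.85 and Atf3 -1.97.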

Other observations

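The test of opposition below was fixed before its result was seen; the lists described first were fixed with the others. Lists with no call in any comparison included genes that changed from 3 h to 6 h. In low potassium, 9 of 32 glycolysis and hypoxia genes fell and 2 rose (median -0.21, adjusted p = 0.0991), such as the glucose transporter Slc2a1 (-0.84) and Ndrg1 (-0.93) down and Mxi1 (1.38), a MYC antagonist, up. Heat shock genes had 6 of 19 that fell and 0 that rose (median -0.26, adjusted p = 0.124), such as the co-chaperones Fkbp4 (-0.69) and Ahsa1 (-0.53). NF-kB and inflammatory genes had 3 of 17 that fell (median -0.33, adjusted p = 0.392), Cxcl1 (-1.62), Socs3 (-0.92) and Ccl20 (-0.74). p53 target genes had 2 of 18 that rose, among them Sesn1 (1.35), and 4 that fell, among them Perp (-1.38) and Ccng1 (-0.77; list median -0.04, adjusted p = 0.991). Histone deacetylase and chromatin genes had 5 of 17 that rose, such as Foxp1 (1.03) and Ep300 (0.90), and 3 that fell, such as Hdac3 (-0.80; list median 0.16, adjusted p = 0.371).

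Anti-apoptotic genes had 2 of 15 that fell in low potassium, Akt1 (-0.76) and Bag1 (-0.70; list adjusted p = 0.991). RAF-MEK-ERK, JNK and AKT pathway components had 2 of 16 that rose, Map3k12 (0.60), a kinase upstream of JNK, and Pik3ca (0.70), and 2 that fell (list adjusted p = 0.989). Cell cycle genes had 1 of 31 that rose and 1 that fell, Ccne2 (0.41) and Cdk4 (-0.76; adjusted p = 0.991), and oxidative phosphorylation genes 2 of 29 that rose and 3 that fell (median 0.0087, mean -0.027, adjusted p = 0.991). Endothelial and fibroblast markers had 0 of 8 past the threshold (median 0.017, mean -0.016, adjusted p = 0.991), and Purkinje and GABAergic neuron markers had 1 of 10 that rose, Rora (1.07), and 1 that fell, the calcium buffer Pvalb (-1.17; adjusted p = 0.989). Adjusted over the list alone, the counts up and down were 2 and 9 for glycolysis, 1 and 7 for heat shock, 0 and 3 for NF-kB, 3 and 5 for p53, 5 and 3 for chromatin, 0 and 2 for anti-apoptotic, 2 and 2 for pathway, 0 and 1 for cell cycle, 2 and 2 for oxidative phosphorylation, 0 and 0 for endothelial and 1 and 2 for Purkinje genes. None of these 11 lists passed for GW5074 at 3 h, at 6 h or on average, with or without pairs.

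A hypothesis was that GW5074 at 6 h may run against the change from 3 h to 6 h in low potassium. Of the 349 paired calls at 6 h, 150 were also called from 3 h to 6 h in low potassium, and 122 of these had the opposite direction, but both use the low-potassium arrays at 6 h. With the time change computed without the pair tested, the correlation across probe sets was -0.0123 in pair A, -0.155 in pair B and -0.0886 in pair C. The 3 h pairs, treated alike, gave -0.126 (A), 0.0689 (B) and 0.0128 (C), so a 3 h pair lies within the range of the 6 h pairs. The bound of -0.1 in all 3 pairs was not reached and none was above 0, so the highest value, -0.0123, leaves the question open.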
